A study of Mus musculus with 6 samples.

How the data were processed

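Cells were sorted by the submitters from digested hindlimb muscle of C57 black 6 mice aged 7 to 9 days, per the labels. Staining for CD34 and Sca1 was used to separate PICs from satellite cells in the sort. PICs are known in the field as interstitial cells that express PW1, the product of Peg3, and satellite cells are the resident stem cells of skeletal muscle. Each population has 3 arrays that the labels call biological replicates. Per the labels' protocols, biotinylated cRNA was made from 200 ng of total RNA and hybridised to 1-colour Affymetrix arrays, 1 sample to an array.

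The deposited table holds 1 value for each of 45037 probe sets on each of the 6 arrays. Per the submitters' processing notes the values come from GCRMA, a method that combines a background correction by probe sequence with quantile normalization and a summary per probe set; no version is given in the sources used here. The deposited values are linear intensities rounded to whole numbers (100% of values), with a lowest value of 2 and a median of 10 on each array. They were taken to log2 before any test. Rounding makes steps between the lowest values coarse on the log2 scale, and GCRMA pulls unexpressed probe sets towards a common floor, which narrows their spread. Scanner files, detection calls and scan dates were not used here, so scan batches were not tested. The precision of each mean is limited by the number of arrays, 3 per population.

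Probe sets were named through the platform annotation given with the data, with symbols updated by gene number against RefSeq names of the GRCm38.p6 assembly. Of all probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none listed, and 34741 of those with 1 symbol were matched by gene number. No position is printed because the array values name no genome build. Probe sets with several symbols or none were left out of the gene tests; 2173 of them passed the filter on low values, and 412 of these were called in a fit of their own, 204 higher in PICs and 208 higher in satellite cells. Ly6a, which encodes Sca1, had no probe set named for it and was not analysed here.

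Probe sets were kept when their log2 value was above 4 (linear intensity above 16) on at least 3 of the 6 arrays, whatever the population, which left 20606 probe sets, 18433 of them with 1 symbol. For each gene the kept probe set with the highest mean over all 6 arrays was used, giving 10855 genes. Among called genes, 378 rested on a probe set whose name marks possible hybridisation to related transcripts. Differences are log2 values of PICs minus satellite cells. They were tested with limma 3.58.1 (lmFit and eBayes, two-sided, no trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested. A gene was called when its adjusted p was under 0.05 and its difference was at least 1 on the log2 scale. Where all 3 arrays of a population lay at or under 4, no level was taken as measured there; the fold is then a lower bound, the mean of the other population minus 4, written as "at least".

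A total of 28 gene lists of cell types, pathways and technical signals were fixed before the data were examined. They were tested with camera (limma, preset correlation of 0.01), with Benjamini-Hochberg adjustment over the lists with at least 4 tested genes. Camera with a correlation estimated per list and the rotation test fry were run as alternatives. With an estimated correlation, camera takes its degrees of freedom from the residuals of the 6 arrays. With the preset correlation it takes them from the number of genes. A further 6 lists (adult fast fibre, marrow granulocyte, cartilage, cytokine response, dystrophin complex and axon guidance) were written after the results had been seen, the adult fast fibre list before the values of its own genes were examined.

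Genes named in the text follow a rule fixed before the data were examined. It takes the sorting and definition genes Ly6a, Cd34 and Peg3 as checks. It then takes the 12 called genes with the largest fold in each direction without overlap between arrays, up to 4 called genes of largest fold per list and direction, and genes whose probe sets were called in opposite directions. List members that were not called are named with their values. Pax7, Myf5, Vcam1, Dcn, Mki67 and Pdgfd, and the genes named for the added lists, fall outside this rule and were chosen after their values were seen.

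The replicate numbers are shared by both populations, and the labels do not say whether a number marks a shared preparation. Deviations from the population mean over 10855 genes were therefore correlated between PIC and satellite arrays. Correlations across genes for arrays of equal number were 0.623, 0.222 and 0.579, against values from -0.568 to 0.0363 for unequal numbers. Genes are not independent replicates, so no p is attached. The pairing thus comes from the data and not from the labels. The tests reported are without the replicate number. A fit with the replicate number as a block is given where it changes the call of a list or of a named gene.

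Alternatives covered the filter on low values, the normalization between arrays, the summary of probe sets, the variance moderation, array weights (statmod 1.5.0), the block, the thresholds and leaving out each array in turn. The array weights were 6.48 for PICs replicate 2 and 3.41 for satellite replicate 2, and 0.269 to 0.645 for the other arrays. The weighted fit thus rests mostly on the arrays numbered 2. Leaving out both arrays numbered 1 or both numbered 3 was added after the data had been seen. The fit was tested on simulated data built for this comparison over 10855 genes. Of 250 simulated changes at each size, 34% were called at a true log2 difference of 1, 89.6% at 2 and 95.2% at 3, and none at 0.5, where 5.2% reached the adjusted p alone. At a true difference of 1, 55.2% reached the adjusted p, and the fold threshold itself limits the calls. Among the unchanged genes 13 were called and 28 reached the adjusted p, summed over 5 runs. Far fewer genes were changed in each run than reached the adjusted p in the data (6106). The adjustment is therefore stricter in the simulation, and these rates and counts do not carry over to the data. A list of 20 genes shifted by 1 was found in 5 of 5 runs, with 0 of 135 unshifted lists past the threshold. The simulated noise was drawn independently for each gene. In the data the estimated correlation within a list was 0.34 for myogenic progenitor markers and 0.91 for leukocyte markers. The 0 of 135 therefore gives no rate of false list passes for the data.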

Results

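Transcript levels were measured in PICs and satellite cells sorted from hindlimb muscle of 1-week-old mice, with 3 arrays per population. The design asks how gene expression differs between these 2 muscle-resident populations at this age. Every array had a median intensity of 10, and between 44.7% and 45.5% of its probe sets lay above an intensity of 16. Arrays of the same population correlated at 0.956 to 0.986 over the genes tested (6 pairs), and arrays of different populations at 0.800 to 0.850 (9 pairs). The first principal component held 83.8% of the variance and the second 10.7%.

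PICs and satellite cells differed in 3230 of 10855 genes (29.8%), of which 1815 were higher in PICs and 1415 higher in satellite cells. In 3220 of these genes the 3 arrays of one population all lay above the 3 arrays of the other. Over all genes tested 64.6% were parted in this way, where chance gives 10%. Fitted differences of at least 8-fold were found for 358 genes in PICs and 172 in satellite cells. These counts use the fitted values also for genes at the low value level, where only a bound is measured. In 201 called genes the satellite arrays were all at or under the low value level, and in 128 the PIC arrays were. The median difference over all genes was -0.04.

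Genes with large fitted differences towards PICs included Cxcl9, a chemokine induced by interferon, and Qprt, an enzyme of NAD synthesis. Cxcl9 had a log2 level of 9.37 ± 0.54 in PICs and 3.09 ± 1.62 in satellite cells (SD, n = 3 each), a fitted difference of 6.28 (limma, adjusted p = 0.000768). Qprt differed by 5.94 (adjusted p = 0.000131) and P2ry14, a receptor for UDP-sugars, by 5.53 (adjusted p = 2.84e-05). The adhesion genes Itgb3, Cldn1 and Tenm2 differed by 5.38, 5.35 and 5.30, and Slitrk1, Apod and Kcnk2 by 5.49, 5.29 and 5.27. The satellite means of Cxcl9, Qprt, Slitrk1 and Itgb3 lay under the low value level with at least 1 array above it (Cxcl9 at 2.32, 2.00 and 4.95), so their size is uncertain; the PIC means exceeded that level by 5.37, 5.58, 4.81 and 5.02. Satellite arrays held no measured level of Shisa3, Fez1 and Pcdh20, which were at least 24.6-fold, 25.2-fold and 23.0-fold higher in PICs.

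Genes of myoblast fusion and of the acetylcholine receptor were among those with the largest differences towards satellite cells. Gpr50, an orphan receptor related to melatonin receptors, lay at 9.98 ± 0.17 in satellite cells and 3.09 ± 0.87 in PICs, a fitted log2 difference of -6.89 (SD, n = 3 each; limma, adjusted p = 7.71e-05). Its PIC arrays lay at 2.59, 2.59 and 4.09, around the low value level, which the satellite mean exceeded by 5.98. Mymx and Mymk, which encode the membrane proteins of myoblast fusion, differed by -6.29 and -6.20. Myod1, a transcription factor of the myogenic lineage, differed by -5.84, and Chrna1, the alpha subunit of the muscle acetylcholine receptor, by -6.22. PIC arrays held no measured level of Ryr1, the calcium release channel of muscle, which was at least 38.7-fold higher in satellite cells. The same held for Rapsn (at least 33.7-fold), Arpp21 (at least 58.2-fold), Cnr1 (at least 37.1-fold), Mylk4 (at least 26.3-fold), Popdc2 (at least 20.9-fold) and Pitx3 (at least 19.1-fold).

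Cd34 and Peg3 served as checks of the sort and of the cell definition. Cd34 was 3.79-fold higher in PICs, at 13.69 ± 0.06 against 11.77 ± 0.10 on the log2 scale (SD, n = 3 each; limma, adjusted p = 6.97e-05). On the probe set used, Peg3 lay at 14.38 ± 0.04 in PICs and 14.19 ± 0.08 in satellite cells, a difference of 0.19 that did not pass the threshold (adjusted p = 0.156). Another Peg3 probe set had linear intensities of 8369, 7353 and 3697 on the PIC arrays and 5664, 4563 and 2900 on the satellite arrays. A further one read 1843, 1926 and 917 against 1182, 1315 and 907. Both were higher in PICs at each replicate number, with overlap between the populations. Ly6a was not analysed here.

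**Figure D1:**
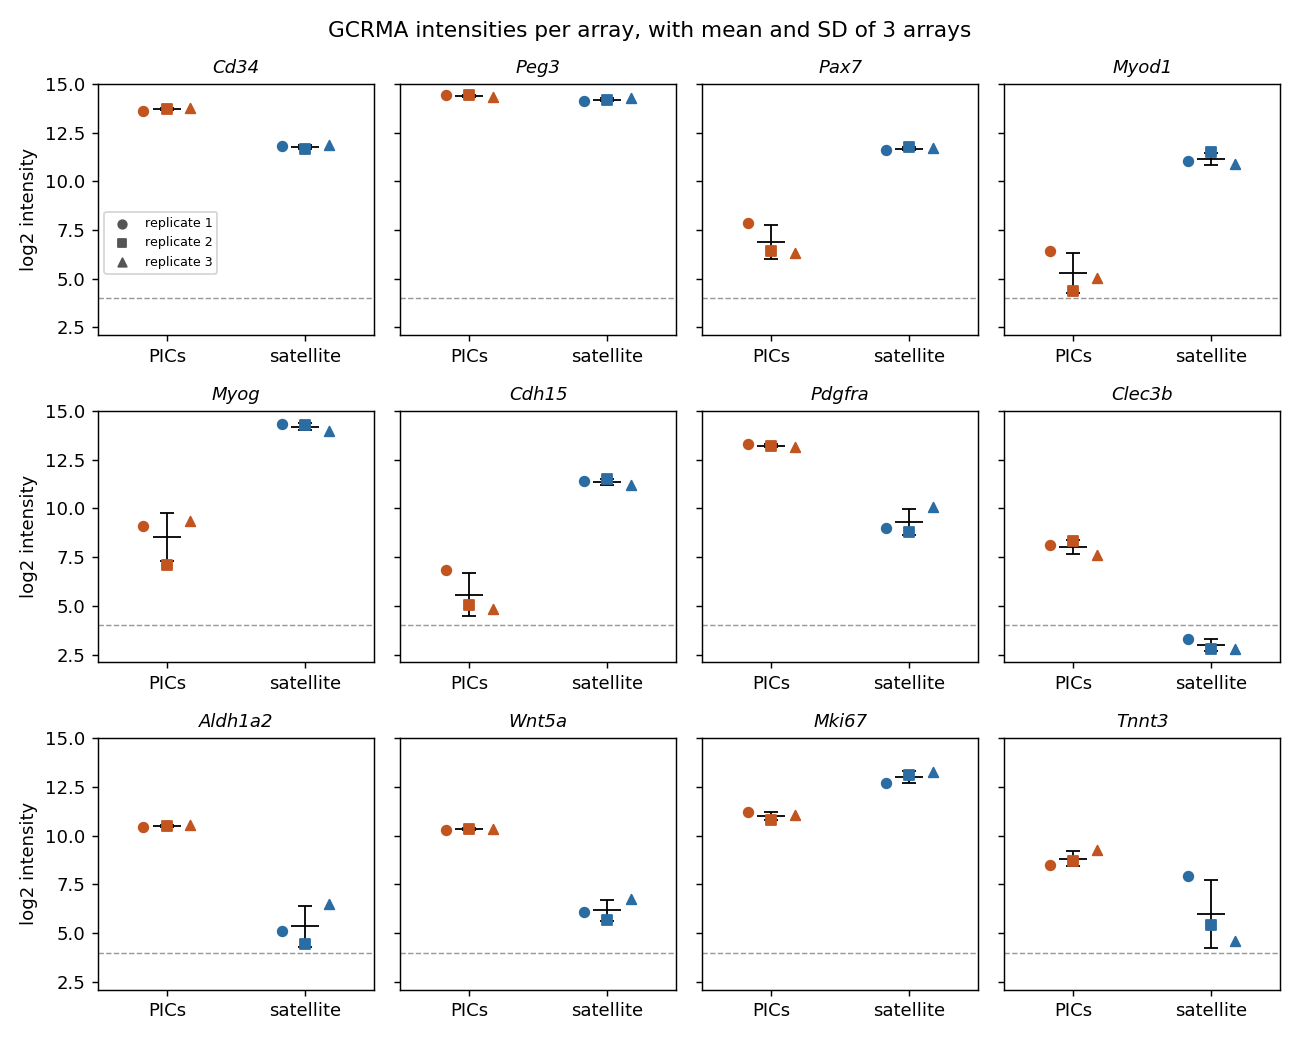
Log2 GCRMA intensity (vertical axis) of 12 genes on each of the 6 arrays, with points marked by replicate number, bars for the mean and SD of 3 arrays, and a dashed line at 4, the low value level. Peg3 lay above 14 on every array on the probe set used, while Pax7, Myod1, Myog and Cdh15 were higher on the satellite arrays and Pdgfra, Clec3b, Aldh1a2 and Wnt5a on the PIC arrays.

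Of the 28 gene lists fixed beforehand, 16 passed the camera test, 9 of them higher in PICs and 7 higher in satellite cells. With a correlation estimated per list none passed, and none had an unadjusted p under 0.05 there. The adjusted p of that test therefore stands beside each of the 16 lists. The rotation test fry passed 19, adding Schwann and glial markers, Notch genes and hindlimb patterning genes. Splits of the 6 arrays that mixed the populations also passed between 9 and 19 lists by camera. In those splits limma called 0 genes, with at most 534 at an unadjusted p under 0.05 against 6654 between the populations. Each mixed split has arrays of both populations on each side, so the population difference enters the residual spread. Few gene calls follow from that by construction. The mixed splits also keep part of the population difference, so their list passes do not show what passes without one. Counts of called members adjusted over the list alone were equal to those over all genes tested for each fixed list except complement and chemokine genes, where 11 of 15 were called instead of 10.

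Markers of myogenic progenitors were higher in satellite cells in 18 of 20 tested members, with 0 higher in PICs and a median log2 difference of -3.08 (camera, adjusted p = 9.33e-07; adjusted p = 0.44 with an estimated correlation). Cdh15, the cadherin of satellite cells, differed by -5.78, the calcitonin receptor gene Calcr by -5.46 and the growth factor receptor gene Fgfr4 by -4.95. Pax7 and Myf5, transcription factors of satellite cells chosen after their values were seen, differed by -4.79 and -3.95. On the probe set used, Pax7 lay at 7.88, 6.44 and 6.34 on the PIC arrays, above the low value level. Another Pax7 probe set had linear intensities of 28, 11 and 6 on the PIC arrays in the same order. Of these only the 28 lay above the low value level. That probe set read 717, 612 and 159 on the satellite arrays. Whether Pax7 was above the low value level in PICs thus depends on the probe set. The members not called were Peg3 and Sdc3, and Sdc3 lay 0.55 higher in PICs (95% interval 0.24 to 0.86, adjusted p = 0.0114).

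Genes of differentiating muscle moved in both directions, 12 of 24 higher in satellite cells and 7 higher in PICs. Their median was -1.74 (camera, adjusted p = 0.0435; adjusted p = 0.729 with an estimated correlation). With the replicate block the adjusted p was 0.102, and without satellite replicate 1 it was 0.479. The median was -0.73 without the filter on low values (adjusted p = 0.013) and -2.84 with a stricter filter (adjusted p = 0.0255). The members higher in satellite cells included Mymx and Mymk, Myog (-5.68), a transcription factor of terminal differentiation, and Tnnt2 (-5.03), the troponin T of cardiac and immature muscle. The members higher in PICs included Tnnt3 (2.84), Tnnc2 (2.31) and Myl1 (2.09), which encode proteins of fast fibres, and Casq2 (1.93). Satellite replicate 1 exceeded the mean of the other satellite arrays by a median of 2.36 over those 7 genes, and Tnnt3 lay at 7.91, 5.43 and 4.58 on the satellite arrays. Tnnt3 was not called without any 1 of the 3 PIC arrays or without satellite replicate 2 or 3 (adjusted p = 0.0519 to 0.0802), and neither were Tnnc2 and Myl1; none of the 3 was called without the filter on low values (adjusted p = 0.112 to 0.159). Without both arrays numbered 3, 1 of the 24 genes was called higher in PICs, and without both numbered 1 there were 8. Acta1, skeletal alpha-actin, differed by -0.26 (95% interval -0.77 to 0.25).

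Acetylcholine receptor and synapse genes were higher in satellite cells in 6 of 11 members, and 0 were higher in PICs (median -2.12; camera, adjusted p = 0.00644; adjusted p = 0.44 with an estimated correlation). Without the filter on low values the median was -0.40 (adjusted p = 0.00217). Besides Rapsn and Chrna1 they included Dok7 (-4.08), an activator of the receptor kinase MuSK, and the receptor subunit gene Chrnb1 (-4.05). Premyogenic transcription factors were higher in satellite cells in 9 of 13 members and higher in PICs in 2 (median -2.57; camera, adjusted p = 0.0021; adjusted p = 0.44 with an estimated correlation). Lbx1, a factor of limb muscle precursors, was at least 20.7-fold higher in satellite cells, and Zic1 and Eya1 differed by -5.32 and -4.13. The 2 members higher in PICs were the homeobox genes Meox1 (3.75) and Meox2 (3.42).

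Markers of fibro-adipogenic progenitors, the mesenchymal cells of the muscle interstitium, were higher in PICs in 21 of 23 members and higher in satellite cells in 0. The median was 3.92, or 3.57 with genes at the low value level set to their bound (camera, adjusted p = 2.3e-09; adjusted p = 0.44 with an estimated correlation). Pdgfra, the receptor used to identify these cells, lay at 13.21 ± 0.08 in PICs and 9.29 ± 0.68 in satellite cells, 15.1-fold apart (SD, n = 3 each; limma, adjusted p = 0.000178). Osr1, with a satellite mean under the low value level, differed by 5.03, Cxcl14 by 4.84 and Ebf2 by 4.78, and Clec3b was at least 16.3-fold higher in PICs. The members not called were Prrx1, at 0.79 (adjusted p = 0.00328), and the hyaluronan synthase gene Has1, whose level lay between 4.70 and 10.79 on the PIC arrays (difference 4.06, adjusted p = 0.0894). With the replicate block the adjusted p of Has1 was 0.00413, and it was 0.0271 without PICs replicate 1 and 0.0475 without satellite replicate 3.

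Adipogenic genes were higher in PICs in 7 of 14 members and lower in 1, with a median of 1.17 (camera, adjusted p = 0.0208; adjusted p = 0.44 with an estimated correlation). Without the filter on low values the median was 0.07 and the adjusted p 0.0719. The replicate block gave 9 members higher in PICs and 1 lower. The members higher in PICs included the early regulators Ebf2, Zfp423 (3.75) and Ebf1 (3.15), and Lpl (1.77), lipoprotein lipase. Fabp4, a lipid carrier also found in endothelium, differed by 0.07 (95% interval -0.79 to 0.92), and Pparg, Cebpa and Adipoq did not pass the filter on low values.

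Fibrillar matrix genes were higher in PICs in 19 of 27 members and higher in satellite cells in 0 (median 1.73; camera, adjusted p = 3.06e-08; adjusted p = 0.44 with an estimated correlation). Mfap2, a microfibril protein, differed by 3.64, Col14a1 by 3.21, Col5a3 by 2.87 and the elastic fibre gene Fbln5 by 2.69. The major collagen genes Col1a1, Col1a2 and Col3a1 lay at 13.78 or higher on every array and differed by 0.67, 0.70 and 0.45, under the 2-fold threshold. With the mean of each gene's probe sets the differences were 1.51, 1.52 and 1.10, and all 3 genes were called. Basement membrane genes were divided, with 9 of 20 higher in PICs and 3 higher in satellite cells (median 0.84; camera, adjusted p = 0.00787; adjusted p = 0.581 with an estimated correlation). Col4a5 (3.18), Lama4 (3.05) and Nid2 (2.97) were higher in PICs. Lama5 (-3.94), the laminin receptor subunit gene Itga7 (-2.66) and Dag1 (-1.55), which encodes dystroglycan, were higher in satellite cells.

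**Figure D2:**
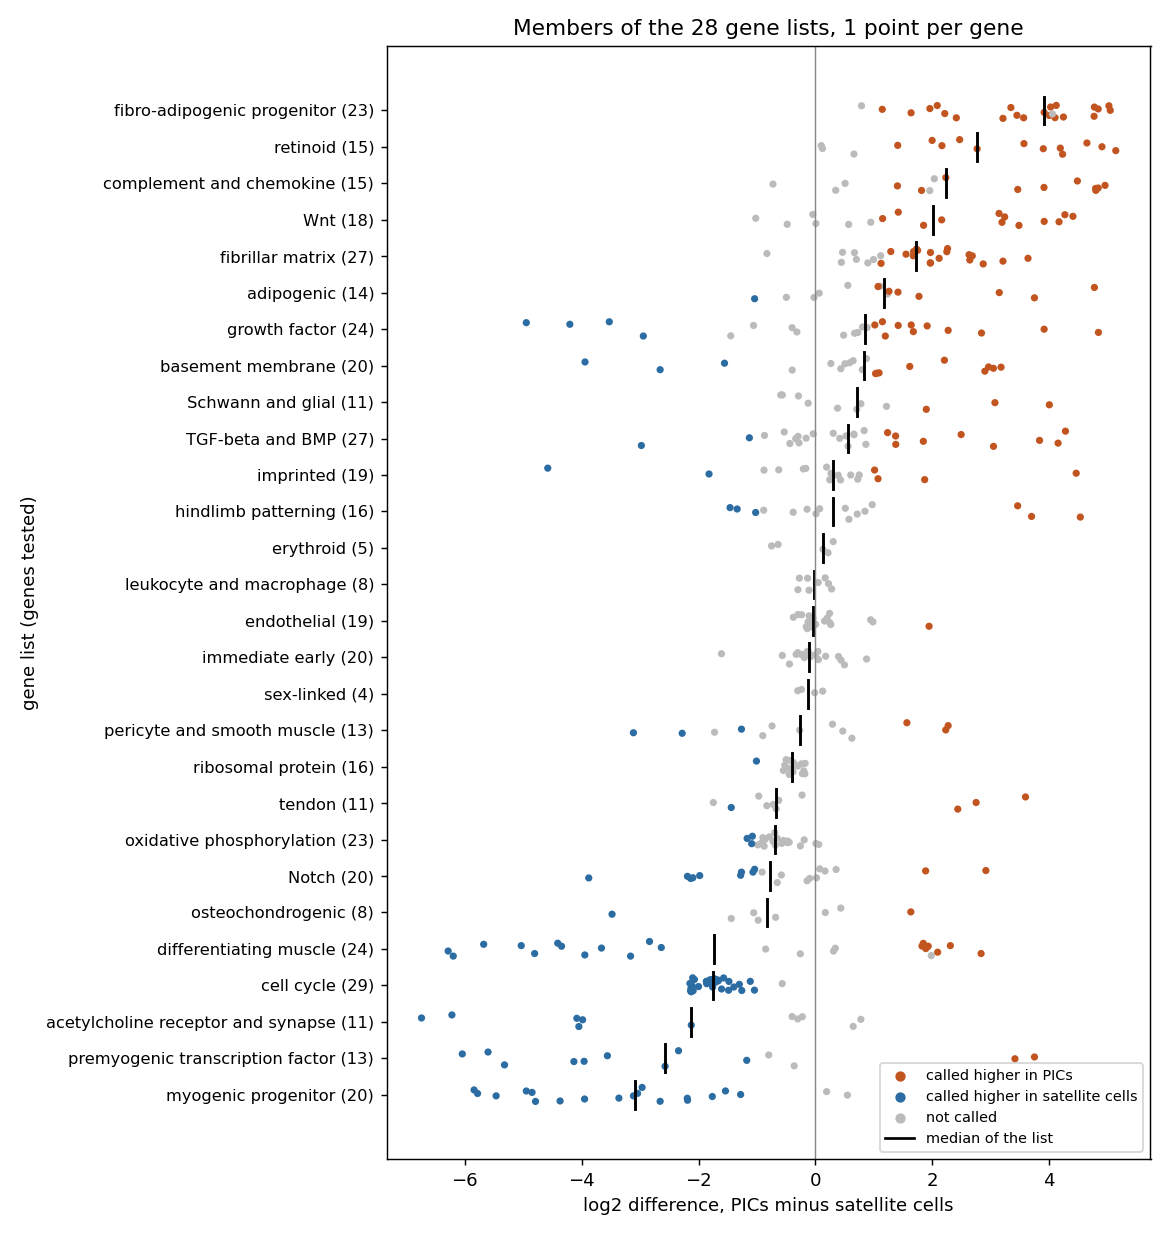
Log2 difference of PICs minus satellite cells (horizontal axis) for each tested member of the 28 fixed gene lists (vertical axis, number of genes in brackets), 1 point per gene, coloured by call, with a black line at the list's median. The highest median is that of fibro-adipogenic progenitor markers (3.92) and the lowest that of myogenic progenitor markers (-3.08).

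Genes of Wnt signalling were higher in PICs in 12 of 18 members and higher in satellite cells in 0. Their median was 2.01, or 1.84 with bounds (camera, adjusted p = 4.79e-05; adjusted p = 0.44 with an estimated correlation), and 0.94 without the filter on low values (adjusted p = 1.55e-05). They included the ligand gene Wnt5a (4.17) and the secreted modulators Sfrp4 (4.41) and Dkk2 (3.92), while Rspo3 was at least 14.8-fold higher in PICs. Axin2, a target gene of the canonical pathway, differed by 0.95 (95% interval 0.15 to 1.75, adjusted p = 0.0486), under the 2-fold threshold; without satellite replicate 3 it was called, at 1.23.

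The TGF-beta and BMP list was higher in PICs in 9 of 27 members and lower in 2 (median 0.56; camera, adjusted p = 0.0416; adjusted p = 0.556 with an estimated correlation). It did not pass with the replicate block (adjusted p = 0.0617), nor without PICs replicate 2 (0.0526), PICs replicate 3 (0.0501) or satellite replicate 1 (0.0587). Bmp5 differed by 4.28 and Gdf10 by 3.05, Bmp7 was at least 7.28-fold higher in PICs, and Fst, which encodes the activin antagonist follistatin, differed by 4.16. Inhbb, an activin subunit gene, was higher in satellite cells (-2.98), with a PIC mean under the low value level. Bmp4 differed by -0.04 (95% interval -0.53 to 0.45).

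Growth factor genes were higher in PICs in 11 of 24 members and higher in satellite cells in 4 (median 0.85, mean 0.36; camera, adjusted p = 0.0416; adjusted p = 0.556 with an estimated correlation). With the replicate block the adjusted p was 0.0617, and without PICs replicate 1 it was 0.115. The block gave 11 members higher in PICs and 6 higher in satellite cells. In the platelet-derived growth factor family the receptor genes Pdgfra (3.92) and Pdgfrb (2.27) were higher in PICs, and the ligand genes Pdgfa (-3.53) and Pdgfc (-2.94) were higher in satellite cells. The ligand gene Pdgfd was higher in PICs (1.64; not called without the filter on low values, adjusted p = 0.0629). Pdgfb was not called (-1.45, adjusted p = 0.0746; 0.0128 with the replicate block, 0.00279 with array weights and 0.0173 without PICs replicate 1). Igfbp6 (4.85) and Fgf7 (2.85) were higher in PICs, and Met, the receptor gene for hepatocyte growth factor, was higher in satellite cells (-4.20).

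Retinoid genes were higher in PICs in 12 of 15 members and higher in satellite cells in 0 (median 2.77; camera, adjusted p = 1.07e-05; adjusted p = 0.44 with an estimated correlation). Aldh1a2 and Aldh1a3, which encode enzymes that make retinoic acid, differed by 5.14 and 4.65. The binding protein gene Crabp2 and the alcohol dehydrogenase gene Adh1 differed by 4.91 and 4.23, and the satellite mean of Crabp2 lay under the low value level.

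Complement and chemokine genes were higher in PICs in 10 of 15 members and higher in satellite cells in 0 (median 2.23; camera, adjusted p = 0.000101; adjusted p = 0.44 with an estimated correlation). Without PICs replicate 1 the median was 3.50. Ccl11 differed by 4.96, Cxcl14 by 4.84, and complement C2 and the cytokine gene Il33 by 4.80 each. Il6 and Ccl2 were not called. Il6 lay at 6.91, 10.48 and 13.00 in PIC replicates 1, 2 and 3 and at 6.34, 8.16 and 10.01 in satellite replicates 1, 2 and 3 (difference 1.96, adjusted p = 0.345; 0.0219 with the replicate block). Ccl2 differed by 2.04 (adjusted p = 0.0512; 0.00319 with the replicate block and 0.00936 without PICs replicate 1). Immediate early genes, which respond to cell handling, had 0 of 20 members called by limma (2 at an unadjusted p under 0.05; camera, adjusted p = 0.919), and with the replicate block 1 was higher in satellite cells. Their median deviation from the population mean was -0.78 and -0.53 on the arrays numbered 1 and 0.90 and 0.45 on those numbered 3, in PICs and satellite cells respectively.

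Cell cycle genes were higher in satellite cells in 28 of 29 members and higher in PICs in 0, with a median of -1.76 (camera, adjusted p = 5.17e-10; adjusted p = 0.44 with an estimated correlation). Kif11, Bub1, Aurkb and Ccna2, which act in mitosis, differed by -2.15, -2.13, -2.13 and -2.12. Mki67, chosen after its values were seen, lay at 11.02 ± 0.20 in PICs and 13.02 ± 0.30 in satellite cells (SD, n = 3 each). The member not called was the replication gene Mcm4 (-0.57, adjusted p = 0.0155).

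Oxidative phosphorylation genes were higher in satellite cells in 3 of 23 members and higher in PICs in 0, with a median of -0.68 (camera, adjusted p = 0.000101; adjusted p = 0.44 with an estimated correlation). The 3 were Ndufs1 (-1.17), Atp5b (-1.09; not called without both arrays numbered 3, at -0.98) and Uqcrc1 (-1.08). Ribosomal protein genes had a median of -0.39 with 1 of 16 called (camera, adjusted p = 0.00644; adjusted p = 0.514 with an estimated correlation). That gene was Rps6 (-1.01), which fell under the 2-fold threshold without PICs replicate 1 (-0.94) or satellite replicate 2 (-0.93).

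Notch pathway genes were higher in satellite cells in 9 of 20 members and higher in PICs in 2, and the list did not pass (median -0.78; camera, adjusted p = 0.101). Its adjusted p was 0.0406 without PICs replicate 1 and 0.0371 without the filter on low values, and without both arrays numbered 3 the count in satellite cells was 4. The ligand gene Dll1 (-3.88), the target gene Hey1 (-2.19) and the Hes family gene Hes6 (-2.13) were higher in satellite cells, whereas Dner differed by 1.89 and Dtx1 was at least 5.48-fold higher in PICs. Hes1, another target gene, differed by -0.10 (95% interval -0.95 to 0.76).

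Markers of other cell types did not pass as lists. Of 19 endothelial markers 1 was called, Eng, at 1.95 higher in PICs (median -0.04, mean 0.18; camera, adjusted p = 0.671). The endothelial list deviated from the PIC mean by medians of 0.82, 0.33 and -1.17 on PIC replicates 1, 2 and 3, and without PICs replicate 3 it passed, higher in PICs (median 0.71, adjusted p = 0.0074), as it did without both arrays numbered 3 (0.41, adjusted p = 0.0123). Cdh5, the endothelial cadherin, lay at 11.07, 10.72 and 8.50 on those arrays and at 10.46, 9.73 and 9.36 on the satellite arrays. It differed by 0.24 (adjusted p = 0.788; called at 1.04 without PICs replicate 3). Pericyte and smooth muscle markers were divided, with Pdgfrb, Cspg4 (2.23) and Myl9 (1.57) higher in PICs and Des (-3.11), Acta2 (-2.28) and Notch3 (-1.26) higher in satellite cells. That list had a median of -0.27 (camera, adjusted p = 0.95), and without PICs replicate 3 its median was 0.66 (-0.65 without PICs replicate 1) and Notch3 was no longer called (-0.94). Without the filter on low values neither Myl9 (adjusted p = 0.0506) nor Notch3 (adjusted p = 0.053) was called.

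Schwann and glial markers were higher in PICs in 3 of 11 members, Cdh19 (at least 9.00-fold), the nerve growth factor receptor gene Ngfr (3.08) and S100b (1.90). The list did not pass (median 0.71; camera, adjusted p = 0.137), but its adjusted p was 0.0391 without PICs replicate 3 and 0.0494 without satellite replicate 1. Leaving out 1 array moved the median between 0.15 (without PICs replicate 1) and 1.20 (without satellite replicate 1), and it was 0.38 without the filter on low values. Tendon markers had a median of -0.67 and a mean of 0.14 over 11 members (camera, adjusted p = 0.919). That median was -0.42 without PICs replicate 3 and -0.29 with array weights. Thbs2 (3.60), Cilp (2.75) and Thbs4 (2.44) were higher in PICs and Mkx (-1.44) was higher in satellite cells, the last not called without the filter on low values (adjusted p = 0.0608) or with array weights (-0.96). With the replicate block 3 tendon markers were higher in PICs and 2 in satellite cells. Osteochondrogenic markers had 1 of 8 called in each direction, Msx1 (1.63) in PICs and Sox6 (-3.48) in satellite cells (median -0.83; camera, adjusted p = 0.919), and with the replicate block 1 and 3 were called. Msx1 was not called without both arrays numbered 1 (adjusted p = 0.0534). Leaving out 1 array moved that median between -1.52 (without PICs replicate 1) and 0.03 (without PICs replicate 3).

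Leukocyte and macrophage markers had 0 of 8 members called by limma, and 0 at an unadjusted p under 0.05 (camera, adjusted p = 0.994). The list held 20 genes with a named probe set, and only these 8 passed the filter on low values. Erythroid markers had 0 of 5 called and 1 at an unadjusted p under 0.05 (median 0.13, mean -0.15; camera, adjusted p = 0.919). The erythroid median was -0.87 without PICs replicate 1 and -0.70 without satellite replicate 2, and the leukocyte median lay between -0.83 (without PICs replicate 1) and 1.16 (without satellite replicate 1). Both lists were high on the arrays numbered 1. The leukocyte list deviated from its population mean by a median of 2.05 on PIC replicate 1 and 2.38 on satellite replicate 1, and the erythroid list by 2.19 and 1.40. Lyz2, lysozyme of myeloid cells, lay at 10.40, 6.63 and 3.00 in PIC replicates 1, 2 and 3 and at 10.84, 6.00 and 4.09 in satellite replicates 1, 2 and 3.

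**Figure D3:**
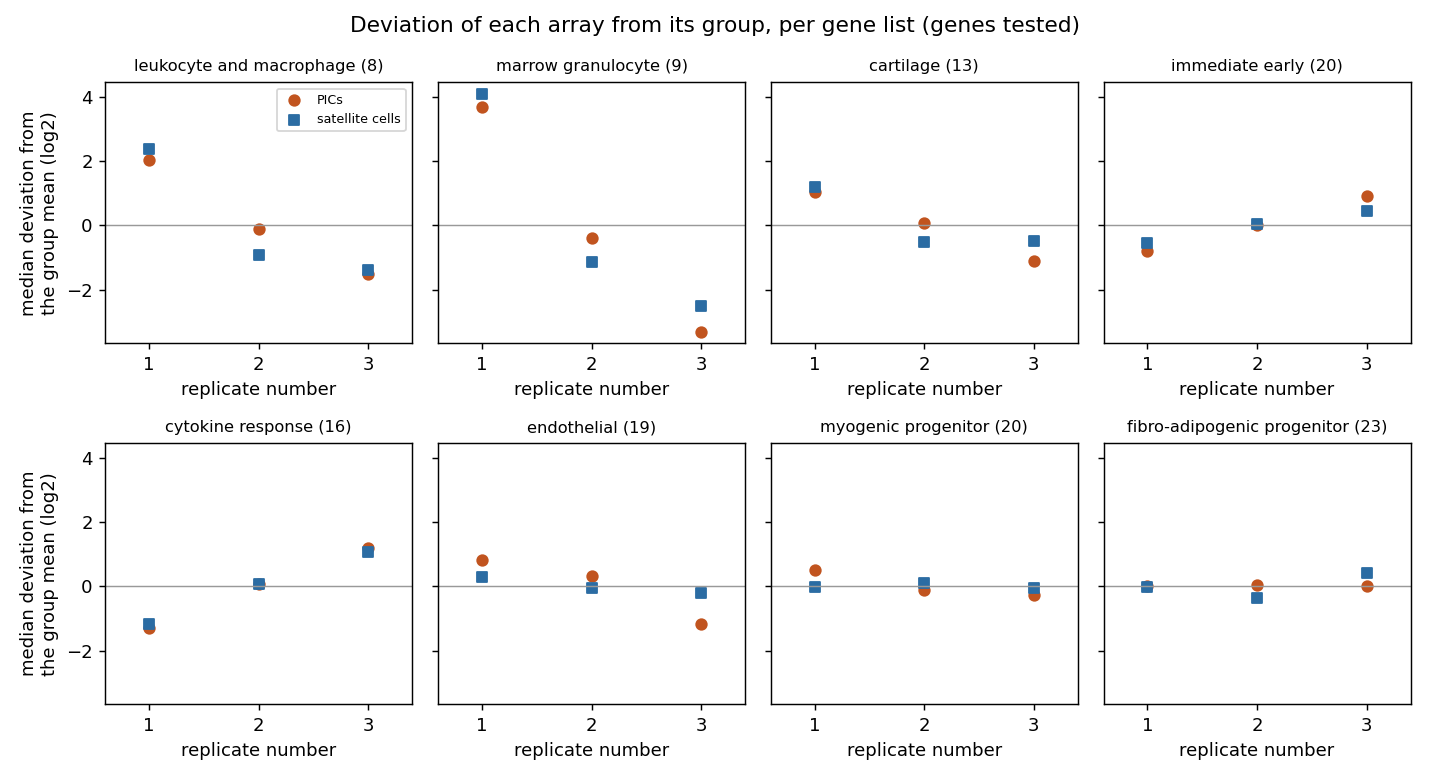
Median deviation from the population mean in log2 units (vertical axis) by replicate number (horizontal axis) for 8 gene lists, with circles for PICs and squares for satellite cells. Leukocyte and marrow granulocyte genes were highest on both arrays numbered 1, immediate early and cytokine response genes on both arrays numbered 3.

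Imprinted genes, the class to which Peg3 belongs, were higher in PICs in 4 of 19 members and higher in satellite cells in 2 (median 0.31; camera, adjusted p = 0.354). Magel2 (4.47), Ndn (1.87), Dlk1 (1.07) and Sgce (1.01) were higher in PICs, and Zdbf2 (-4.58) and Peg12 (-1.82) in satellite cells. The direction of Dlk1 depends on the probe set: another one was called at -1.08, and the mean of its probe sets gave -0.00544. Sgce fell under the 2-fold threshold without PICs replicate 2 (0.99), PICs replicate 3 (0.93) or satellite replicate 1 (0.93), and Dlk1 without PICs replicate 1 (0.97) or satellite replicate 1 (0.80). Igf2 differed by 0.73 (95% interval 0.49 to 0.96) and Meg3 by 0.25 (95% interval -0.03 to 0.52).

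Hindlimb patterning genes were called in 3 of 16 members in each direction (median 0.29; camera, adjusted p = 0.473). The median was 0.19 without PICs replicate 3 and 0.58 with the stricter filter. Shox2 (4.54), Tbx18 (3.70) and Meis2 (3.46) were higher in PICs, and Hoxa9 (-1.46), Hoxc9 (-1.34) and Tbx4 (-1.02) in satellite cells. Tbx4 was not called without PICs replicate 1 (-0.91), satellite replicate 1 (-0.94) or satellite replicate 2 (-0.95). Sex-linked genes had 0 of 4 called by limma and 0 at an unadjusted p under 0.05 (camera, adjusted p = 0.908). Xist lay between 10.17 and 11.05 and the Y-linked gene Eif2s3y between 10.47 and 11.13 over all 6 arrays.

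Probe sets of 1 gene were called in opposite directions for 4 of 4717 genes with over 1 kept probe set. These were Asph, Dlk1, Pdlim5 and Pdlim7, so their direction depends on the probe set. Pdlim7 differed by 1.10 on one probe set and by -2.82 on another, Pdlim5 by -1.03 and 1.74, and Dlk1 by 1.07 and -1.08. Asph had differences from -1.53 to 1.38 over 5 probe sets.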

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

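The removal of both arrays numbered 1 or both numbered 3 was chosen after the data were seen; the other alternatives were fixed before. The count of 3230 called genes stayed within 1.5 times of its value under other filters, normalizations, probe set summaries, moderation, array weights and an adjusted p under 0.01, and no gene called in both had changed direction in the fits that compared shared calls. Leaving out 1 array gave 3029 to 3259 genes (1699 to 1849 higher in PICs, 1330 to 1466 higher in satellite cells) and 15 to 17 lists. With the replicate block 3300 genes were called, 1852 higher in PICs and 1448 higher in satellite cells, 3224 of them shared, with 13 of 28 lists. The block ended the list calls of differentiating muscle, TGF-beta and BMP, and growth factor genes, ended the call of the adult fast fibre gene Smpx (adjusted p = 0.0502) and added Has1, Ccl2, Il6, Pdgfb, Sox10 (1.22), Col2a1 (-1.05) and Tagln (-1.73); it changed no other call among the named genes and lists. Without both arrays numbered 1 there were 3229 genes and 13 lists, with the same 3 list calls ended, and without both numbered 3 there were 3283 genes and 17 lists.

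Without the filter on low values 16 named genes lost their call and with array weights 2 did, along with the list calls of differentiating muscle (adjusted p = 0.119) and growth factor genes (adjusted p = 0.0564). Larger changes followed from the thresholds by their construction. Without a minimum fold 6106 genes passed, 2998 higher in PICs and 3108 higher in satellite cells. A test against a 2-fold difference (treat) called 1679 genes, 1024 higher in PICs and 655 higher in satellite cells. Testing each kept probe set gave 5135 calls among 18433 probe sets. Camera with an estimated correlation passed 0 of the 16 lists. For the adipogenic list the estimated correlation was -0.017, under the preset 0.01, yet its adjusted p rose from 0.0208 to 0.44. A higher correlation between genes thus cannot account for the loss of that list. The cause was not tested further. With the mean of a gene's probe sets 3 named genes reversed, Pdlim7 at -0.86, Dlk1 at -0.00544 and Pdlim5 at 0.70, which follows from their probe sets having opposite signs. Of 154 named genes that were called, 128 kept their call under each alternative that scored named genes and still tested them. The changed thresholds and the test of each kept probe set were not scored for named genes. Of the 16 lists, 12 kept their call except with an estimated correlation. Signal near background leaves bounds in place of folds for the 201 and 128 called genes at the low value level in satellite cells and PICs.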

Other observations

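Of the tests in this part, the added gene lists, the tests on the arrays numbered 1 and those on myogenic transcripts in PICs were chosen after the results were seen. The adult fast-fibre list and its 2 tests were written after the pattern was seen but before the list's own values were examined, and the counts over splits were set before.

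In the axon guidance list 15 of 30 members were higher in PICs and 4 higher in satellite cells (median 1.24). The list was written after the values were seen, so its camera test (adjusted p = 0.0108 over the 6 added lists; adjusted p = 0.656 with an estimated correlation) is no evidence for the group. Plxnc1 (3.99), Slit3 (3.88), Epha4 (3.68) and Sema3c (3.10) were higher in PICs. Plxna2 (-2.20), Sema6a (-2.13) and Plxnb1 (-1.44) were higher in satellite cells, and Sema3a was at least 3.06-fold higher there. In the dystrophin complex list 3 of 10 members were higher in satellite cells and 1 in PICs (median -0.26; camera, adjusted p = 0.888). Sgca, the sarcoglycan of striated muscle, was at least 21.8-fold and Dtna at least 7.52-fold higher in satellite cells, with Dag1 at -1.55, whereas Sgce, the broadly expressed sarcoglycan, was 1.01 higher in PICs; with the replicate block 2 members were higher in PICs and 3 in satellite cells.

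The added marrow granulocyte list had 0 of 9 members called by limma (0 at an unadjusted p under 0.05; camera, adjusted p = 0.997), the cytokine response list 0 of 16 (1 at an unadjusted p under 0.05; adjusted p = 0.997) and the cartilage list 3 of 13 (adjusted p = 0.997). In the cartilage list Epyc (3.93) and Col9a2 (2.58) were higher in PICs and Col11a2 (-1.96) in satellite cells. Col9a2 was not called without both arrays numbered 3 (adjusted p = 0.0923) or without the filter on low values (0.074). Col11a2 was not called there either (0.0872 and 0.129), nor without PICs replicate 2 or 3 or satellite replicate 1 or 3 (0.0562 to 0.0866). The replicate block gave 2 cartilage genes higher in PICs and 5 higher in satellite cells. The cytokine response list deviated by medians of -1.29 and -1.17 on the arrays numbered 1 and 1.19 and 1.05 on those numbered 3, in PICs and satellite cells respectively. Nfkbiz lay at 9.96, 11.49 and 13.12 in PIC replicates 1, 2 and 3 and at 10.48, 11.90 and 13.12 in satellite replicates 1, 2 and 3. With the replicate block 5 of the 16 cytokine response genes were higher in PICs and 2 in satellite cells.

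Over 10855 genes, 69 were at least 2-fold higher on array 1 than on both other arrays in PICs and in satellite cells and 26 were lower, against 2 and 1 for array 2 and 32 and 44 for array 3. On the second principal component the arrays numbered 1 lay at 32.05 in PICs and 27.54 in satellite cells, and those numbered 3 on the other side at -34.84 and -25.21. A single scaling factor per array, which would move all genes alike, is argued against: the median deviations of the leukocyte and immediate early lists, a pair chosen after their deviations were seen, were 2.83 apart on PIC replicate 1 and 2.91 apart on satellite replicate 1. Marrow and blood cell RNA in the first preparation may contribute. Without the filter on low values, 16 of 20 leukocyte genes were higher on array 1 than on both other arrays in both populations. Only 8 of the 20 passed that filter. The count of 16 restates levels already seen, and no independent test was run. The abundant granulocyte genes S100a8 and S100a9 lay at 12.79 and 11.48 on PIC replicate 1 and 13.02 and 12.18 on satellite replicate 1, and S100a8 was at 4.75 and 5.21 on the arrays numbered 3; a gate on CD34 and Sca1 is not stated to exclude such cells, and no biological explanation was tested.

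The fast-fibre genes Tnnt3, Tnnc2 and Myl1 were called higher in PICs, but none of the 3 was called when any 1 of the PIC arrays was left out (adjusted p = 0.0519 to 0.111). Fibre RNA in the PIC arrays could not be told apart from other sources: an independent list of 14 adult fast-fibre genes had a median difference of 0.567 with 8 positive (two-sided exact sign test over genes, p = 0.791), and its members were split (5 higher in PICs and 4 in satellite cells; mean -0.14; camera, adjusted p = 0.997), with Pvalb (2.09), Myh4 (1.56) and Myom2 (1.56, with a satellite mean under the low value level) higher in PICs and Atp2a1 (-4.49), Myh1 (-2.85) and Actn3 (-1.54) higher in satellite cells. The adult fast-fibre list held 26 genes, each with a named probe set, and only 14 passed the filter on low values. Fibre RNA in the first satellite array would lower the PIC excess and not raise it. Whether that array holds such RNA stays open, since on the list of 14 it exceeded the other satellite arrays by a median of 0.694, in 13 of 14 genes (exact sign test over genes, p = 0.00183). Genes are not independent replicates, so both sign tests describe the genes of the list and not the spread between preparations. Satellite cells also express some of these genes, and a difference in the populations' own expression remains untested.

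Some myogenic transcripts were measured in PICs well above the low value level (Myog 8.52 ± 1.24, SD, n = 3). For others, among them Ryr1, Rapsn, Pitx3 and Lbx1, the PIC arrays held no measured level. RNA of the whole satellite population carried into PICs would shift progenitor and differentiation genes alike. From PIC replicate 2 to 3, 11 differentiating muscle genes shifted by a median of 0.608 and 18 progenitor genes by -0.0587, a difference of 0.666 (permutation test over genes, two-sided, p = 0.0053); from replicate 2 to 1 it was -0.532 (permutation p = 0.322), and with single arrays on each side this source stays open. RNA of committed myocytes may contribute to part of it, but 54.5% (6 of 11) of the differentiating genes rose by over 0.5, which leaves it open. Expression of these genes in PICs was not tested.

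The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 3230 genes, in 1 of the 10 splits, and the highest of the other splits was 0 (limma; at most 534 genes at an unadjusted p under 0.05). Mixing the populations adds their difference to the residual spread, so that 0 is no support for the 3230 genes. For the gene lists 4 of the 10 splits passed as many as the real one, with 16 lists in the real split and 19 in the highest other. Both splits with 19 lists kept the arrays numbered 1 together, but the other mixed splits that did so passed 13 and 12 lists. With the replicate block 13 lists passed between the populations. Among the splits that part all 3 replicate pairs as the real one does, the others called 0 genes and passed 12, 14 and 18 lists.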
